A study of Mus musculus with 6 samples.

How the data were processed

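RNA was sequenced from pancreatic islets of 12-week-old mice in 6 libraries, 3 from mice lacking pyruvate carboxylase in their β-cells (labelled KO here) and 3 from wild-type (WT) littermates. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into strand-marking libraries and sequenced as paired reads. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1, edgeR 3.16.5 and the mouse build mm10, with no role or order for each tool.

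The values used are whole-number read counts per gene and library, as deposited and per the file headers not normalized. The table lists 13702 genes under identifiers that begin with ENSG and symbols in capitals, and its pathway terms carry the prefix that KEGG uses for human. None of the identifiers (0) is in the mouse gene name table used here, while 11746 of the symbols also name a mouse gene when case is ignored. These identifiers do not go with the mouse organism label or with mm10, and how the reads were assigned to them is not given in the sources used here. A count is therefore the number of reads assigned to a human-named gene, and a mouse gene whose reads do not reach that name has no usable value. No gene is listed with 0 counts in every library. A further 6 per-sample columns, which repeat the library names and per the file headers hold normalized values, were not used. A row without an identifier (1) stayed out of all totals, and it and several genes that the naming rule below covers are not reported here. No coordinates are given, because the table has none and the reference used here is a mouse annotation.

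Groups and replicate numbers came from the sample titles. The labels number the libraries but do not say that each came from a separate animal, so p-values measure only the spread between these libraries, which may be technical. Total counts per library ran from 35906 in WT replicate 1 to 377876 in WT replicate 2, so a single count corresponds to 27.9 CPM (counts scaled to a fixed library total) in the shallowest library and 2.65 CPM in the deepest. A count of 0 was taken to allow up to 3 counts. Intervals are exact Clopper-Pearson intervals at 95%, and intervals and floors cover counting error only.

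Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, the quasi-likelihood F test (two-sided) on genotype alone, and Benjamini-Hochberg adjustment at 0.05. CPM values are on TMM-scaled library sizes unless a share of all counts is named. Log2 fold changes are KO minus WT, with a standard error taken from the F statistic. Where a group had 0 counts, the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts the ratio of summed counts is given with its interval. The tests were tried on simulated data made from the fitted means, dispersions and library sizes of the 2560 tested genes with 200 changed genes. For KO against WT at the fitted dispersions, 8% of genes changed 4-fold and 85% of genes changed 16-fold were recovered, with 2 false calls among 95. At a dispersion of 0.05 in every gene, 97% of 4-fold and 100% of 16-fold changes were recovered, with 15 false calls among 212. The simulation drew all 6 libraries independently, with the same dispersion in both groups. It lacks the near-identical KO libraries and unlike WT libraries described below, so its recovery and false calls may not hold for these data.

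Gene lists (30) were fixed before the data were examined: β-cell identity, exocytosis and excitability, disallowed genes, dedifferentiation, p53 targets, senescence, the senescence secretory phenotype, cell cycle, pyruvate and citrate cycle metabolism, glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, redox, endoplasmic reticulum stress, interferon, NF-kB, immediate early genes, prolactin response, and markers of α-, δ-, PP and ε-, acinar, ductal, endothelial, mesenchymal, myeloid, lymphoid, Schwann, erythroid and adipose cells. Their mouse symbols were matched to the table ignoring case, with a hand-written table for human names that differ. Lists with at least 5 tested members (13) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. Marker lists for squamous epithelium and fibrous connective tissue were written after the libraries had been examined. Named genes followed a rule set before the data were examined: the targeted gene, then the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 4 members of each list with the smallest p, and 22 islet, p53 and senescence genes wherever measured.

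The alternatives were DESeq2 size factors, library totals, no low-count filter, a mean of at least 5 CPM, leaving out each library, the replicate number as a block, leaving genes over 1% of counts out of the library sizes, DESeq2 1.42.0, limma-voom, and other thresholds and list tests. The fit of the KO columns summed to 1 library and the fit without WT replicates 2 and 3 were chosen after seeing the data, as was the use of an estimated correlation in settings other than the planned fit. Other pseudocounts and quantile normalization were not run, since they apply to normalized values.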

Results

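Gene expression was measured by RNA sequencing in islets of mice lacking pyruvate carboxylase in β-cells, the insulin-secreting cells of the islet, and in islets of wild-type littermates, with 3 libraries per genotype. Pyruvate carboxylase is the mitochondrial enzyme that makes oxaloacetate from pyruvate. The comparison asks which genes differ without it, and the series title names p53 activation and β-cell senescence as its subject. Total counts were 35906, 377876 and 135441 in WT replicates 1, 2 and 3, and 225561, 225074 and 224898 in KO replicates 1, 2 and 3. Genes with at least 1 count numbered 3294, 12193 and 8298 in the WT libraries and 7617, 7676 and 7670 in the KO libraries. All values are counts on human-named genes in libraries labelled mouse.

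The targeted gene had too few counts to be compared. Whether depth or the assignment of reads to human names limited it was not tested. PC (ENSG00000173599), the human name for pyruvate carboxylase, had 0, 4 and 0 counts in WT replicates 1 to 3 and 0 counts in each KO library. The 0 of 675533 counts over the KO libraries allows up to 4.44 CPM. PC did not enter the filtered test, and in the edgeR fit without a filter its adjusted p was 0.409. The labels were therefore not checked by the targeted gene. Of the 22 genes set for reporting in any case, 16 were listed in the table and 4 were deep enough to be tested. The islet hormone genes INS, UCN3, GCG and SST, the β-cell transcription factor gene PDX1 and the glucose transporter gene SLC2A2 were not listed under these names. They therefore have no value here. PPY and NKX6-1 had 1 and 2 counts over all libraries.

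The WT libraries differed from one another in the tissue genes they held. In WT replicate 2, markers of squamous epithelium, the layered lining of skin and oesophagus, took 21.8% of all counts, against 0.0975% and 0.135% in WT replicates 1 and 3 and 0.0582% to 0.0749% in the KO libraries. The keratin genes KRT13 and KRT4 led that library with 19353 and 18963 counts. In WT replicate 3, markers of fibrous connective tissue took 1.48% of counts, against 0.150% and 0.0495% in the other WT libraries and 0.308% to 0.320% in KO. KERA, which encodes the corneal and connective tissue proteoglycan keratocan, had 256 counts there and 0 in each of the other libraries. Ribosomal protein genes took 3.10% of counts in WT replicate 2 and 0.666% to 0.956% in the other 5 libraries. By Spearman correlation WT replicate 1 was closer to the KO libraries (0.573 to 0.576) than to WT replicates 2 and 3 (0.346 and 0.391). The genes ranked 1 and 2 in WT replicate 1 had similar counts in WT replicates 1 to 3 despite unequal totals. EIF4G2 had 1323, 1323 and 1268, and DDX5 had 659, 657 and 676. As a share of all counts, EIF4G2 stood at 36850, 3501 and 9362 CPM, against 26190 to 27450 in KO. Why these counts were similar was not tested. The 3 KO libraries were close to identical. Over genes with at least 20 counts in a pair, the chi-square divided by its degrees of freedom was 1.96 to 2.02 for the KO pairs and 18.1 to 35.4 for the WT pairs. The ratio is 1 at sampling noise. The KO libraries were kept as 3 samples, as the labels give them, which does not show that they came from separate RNA samples.

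**Figure D1:**
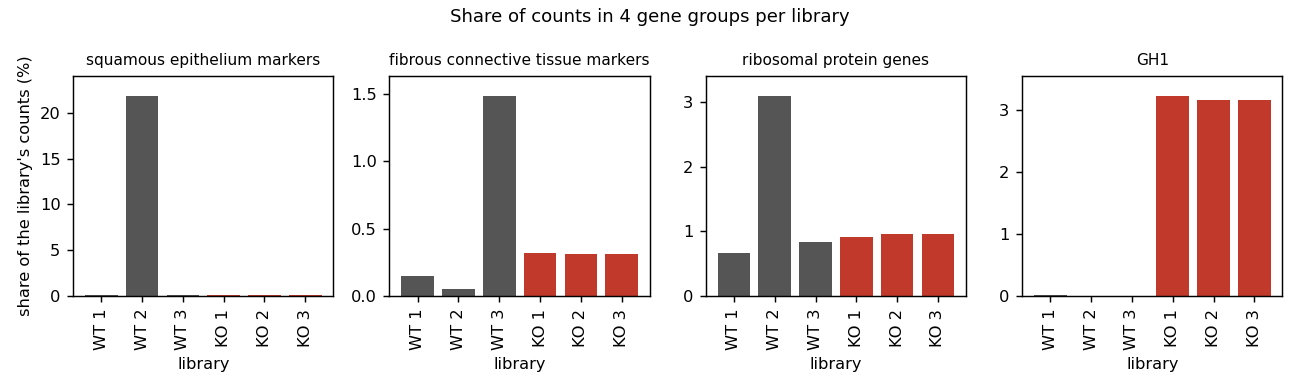
Bars give the share of each library's counts (%, linear axes from 0) taken by squamous epithelium markers, fibrous connective tissue markers, ribosomal protein genes and GH1, with WT libraries in grey and KO libraries in red. Squamous markers reach 21.8% in WT replicate 2, connective tissue markers 1.48% in WT replicate 3, and GH1 3.17% to 3.23% in the KO libraries.

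The largest rise in KO libraries by count was that of GH1 (ENSG00000259384), the human gene for pituitary growth hormone. GH1 had 7285, 7123 and 7132 counts in the KO libraries and 7, 6 and 5 in the WT libraries, or 30060 ± 509 against 78.6 ± 88.0 CPM (SD, n = 3 each). The log2 fold change was 8.86 ± 1.79 (SE), with an adjusted p of 0.0279 in edgeR. It took 3.17% (95% interval 3.09 to 3.24) of the counts of KO replicate 2, the lowest share in KO, and 0.0195% (0.00784 to 0.0402) of WT replicate 1, the WT library with the highest share. Its close relatives GH2 and CSHL1 had 1 to 4 and 8 to 14 counts per KO library, and the division of reads among this family is uncertain. Without WT replicate 2, WT replicate 3 or any 1 KO library, the GH1 call was lost, while its log2 fold change was 8.54 to 9.05 in those 5 fits (adjusted p at most 0.143 over all alternatives).

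Of 2560 genes tested, 206 changed, 129 of them higher and 77 lower in KO. This split moved with the setting. It was 221 higher and 218 lower without a low-count filter, and 816 and 711 without WT replicate 1. With the replicate number as a block it was 106 and 31. Of the 12 largest rises, 9 were of genes with no count in any WT library. NEFM, which encodes a neurofilament subunit, was at least 29.7-fold higher (51, 47 and 45 counts in the KO libraries), and SHANK3, a postsynaptic scaffold gene, at least 16.4-fold higher. CACNB2 and CACNG2, which encode calcium channel subunits, were at least 20.3-fold and 16.8-fold higher. CPEB1, which encodes an RNA-binding regulator of translation, was at least 37.4-fold higher, DNAJB5 at least 23.5-fold, ISCA2 at least 21-fold, EYS at least 18.9-fold and AFP at least 12.9-fold. MYH4, a myosin heavy chain gene of a family with similar members, had 1 WT count and 324 KO counts, a ratio of 202 (interval 36 to 8010). GUCY1A3, which encodes a subunit of soluble guanylate cyclase, had 1 and 303 counts, a ratio of 189 (33.7 to 7500). Adjusted p in edgeR was 0.012 for MYH4 and GUCY1A3 and 0.0237 to 0.0279 for the others. In WT replicate 1, the shallowest library, 81 of the 129 higher genes had 0 counts. The floors and ratios above pool TMM-scaled sizes of 38861, 250061 and 158416 in WT replicates 1, 2 and 3. They therefore rest mostly on WT replicates 2 and 3, which held genes of other tissues. Against WT replicate 1 alone the floors would be much lower.

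The largest falls included epithelial genes that were abundant in WT replicate 2. SPINK5, a protease inhibitor gene of squamous epithelium, had 2, 8563 and 15 counts in the WT libraries and 1, 2 and 2 in KO (log2 fold change −10.56 ± 2.74 SE, and −3.30 without WT replicate 2). S100A8, which encodes a calcium-binding protein of neutrophils and epithelium, had 3, 3247 and 12 against 3 in each KO library (log2 fold change −8.38, and −2.46 without WT replicate 2), and RPL23A, a ribosomal protein gene with many pseudogene copies, had 4, 330 and 9 against 3, 3 and 1 (−5.61, and −2.74 without WT replicate 2). SASH1 had 225 of its 258 WT counts in that library, with a log2 fold change of −4.30, −2.70 without WT replicate 2 and −1.29 against WT replicate 1 alone. HSPA2, a gene of the HSP70 chaperone family whose members are similar, had 3, 28 and 12 WT counts and 0 in KO, at least 22.9-fold lower. HSPH1, another heat shock gene, went from 293 ± 202 to 8.38 ± 4.22 CPM (log2 fold change −5.04 ± 0.86 SE). SLCO5A1 and CAPRIN2 fell by 4.36 and 4.22 on the log2 scale. PRICKLE2 had 31 WT counts and 1 KO count, a ratio of 49.7 (8.28 to 2020), and GTPBP4 42 and 2, a ratio of 33.6 (8.75 to 287). TNRC18 and PPM1L each had 29 WT counts and 2 KO counts, a ratio of 23.2 (5.88 to 201). Adjusted p for these 12 genes ran from 0.0237 to 0.0469 in edgeR.

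The groups did not overlap for 205 of the 206 changed genes and for 893 of the 2560 tested genes. Chance gives 10% only if the 6 libraries vary independently. The near-identical KO columns may not do so, and chance would then give a higher share. No excess over chance is therefore read from these counts. The count of changed genes rested on single libraries, WT replicate 3 excepted. Without WT replicate 3, 121 of the 198 called genes were shared with the 206, so the set of genes changed though its size did not. The count was 1527, 11 and 198 without WT replicates 1, 2 and 3, and 3, 4 and 16 without KO replicates 1, 2 and 3. With WT replicates 2 and 3 both left out it was 766, and with the KO columns summed to 1 library it was 0, with 301 genes at an unadjusted p under 0.05 in edgeR; both fits were chosen after seeing the data. Each sets 1 library against 3, so the lone library is assumed to vary like the other group, and the spread comes from the near-identical KO columns in the first fit and from the unlike WT libraries in the second. No gene (0) passed an adjusted p of 0.01 in edgeR, with 729 at an unadjusted p under 0.05, while DESeq2 called 68 and limma-voom 20 at that level. Of the 24 genes with the largest changes, MYH4 and GUCY1A3 passed the threshold with each library left out in turn. The other 22 lost their call without KO replicate 1 or KO replicate 2, most of them also without KO replicate 3 or WT replicate 2. PRICKLE2, GTPBP4, TNRC18, CAPRIN2 and PPM1L also lost it without a filter and at a mean of 5 CPM, TNRC18 and PPM1L with DESeq2, and SPINK5 and S100A8 with limma-voom.

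**Figure D2:**
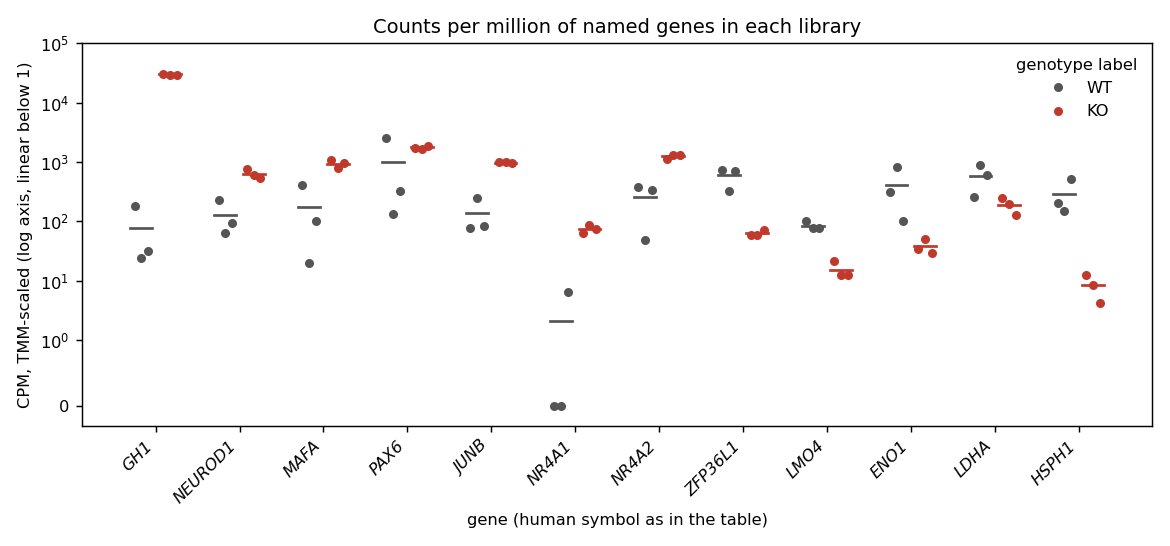
Points give TMM-scaled CPM (log axis, linear below 1) of 12 named genes in each library, WT in grey and KO in red, and horizontal lines give group means over 3 libraries. GH1 lies at 30060 CPM on average in KO and 78.6 in WT, NEUROD1 at 626.8 and 130.1, and HSPH1 at 8.38 and 293.

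Genes of β-cell identity and function were mostly out of reach. Of 32 list members 15 were listed and 5 tested, and of these NEUROD1, which encodes a transcription factor of endocrine cell differentiation, rose. NEUROD1 stood at 627 ± 110 CPM in KO and 130 ± 89.2 in WT (SD, n = 3; log2 fold change 2.41 ± 0.60 SE; adjusted p 0.045). Its counts in WT replicates 1 to 3 were 9, 16 and 15, or 232, 64.0 and 94.7 CPM. The sizes of WT replicates 2 and 3 include counts of other tissues' genes, so the size of this rise depends on the scaling. MAFA, which encodes a transcription factor of mature β-cells, had 253, 190 and 227 counts in KO and 16, 5 and 16 in WT (adjusted p 0.099). PAX6 and FOXA2 had adjusted p of 0.544 and 0.664. Adjusted over the list alone, 2 genes were higher. Of 13 tested genes of exocytosis and excitability, CACNB2 and the sodium channel gene SCN9A rose and 11 did not pass. SCN9A had 3 WT and 77 KO counts, a ratio of 16 (5.28 to 79.4), and ATP2A2 and KCNMA1 had adjusted p of 0.085 and 0.109. Adjusted over the list alone, the count was also 2. By camera the adjusted p was 0.213 for the identity list and 0.0712 for exocytosis. Both lists were called higher with the replicate number as a block (0.0340 each), without WT replicate 1 (0.0277 and 0.00169), without a low-count filter (0.00749 and under 0.001), at a mean of 5 CPM (0.00354 and under 0.001) and with the KO columns summed (0.0394 and 0.00233). With an estimated correlation, tried in each setting after the data were seen, none of these calls held: both adjusted p were 0.734 in the planned fit and 0.574 to 0.961 in the fits just named. At the preset correlation both were 0.406 without WT replicate 2, and against WT replicate 1 alone both lists pointed lower (0.525 and 0.606). In this paragraph the 3 rises were lost without WT replicate 2 or any 1 KO library, and NEUROD1 also without WT replicate 3 and with library totals (adjusted p 0.0616; 0.00226 to 0.626 over all alternatives).

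Disallowed genes, which are normally kept low in β-cells relative to other tissues, were the only list that camera called, and that call was lost without KO replicate 1, 2 or 3 (adjusted p 0.0656, 0.0797 and 0.112), without a low-count filter (0.263) and at a mean of 5 CPM (0.201). Exocytosis was called in the fit without KO replicate 1 (0.0446, and adjusted p 0.775 with an estimated correlation). Of 9 tested members, 3 fell (ZFP36L1, LMO4 and MAF), none rose (0), and 6 did not pass; adjusted over the list alone, 5 fell. The list's adjusted p was 0.00257 by camera at the preset correlation and 0.0282 by fry. With an estimated correlation the camera adjusted p was 0.313. ZFP36L1, which encodes a protein that promotes messenger RNA decay, stood at 62.8 ± 7.20 CPM in KO and 594 ± 235 in WT (log2 fold change −3.22 ± 0.56 SE; adjusted p 0.0237). LMO4 and MAF, which encode a LIM-domain protein and a transcription factor, fell by 2.36 and 2.41 on the log2 scale (adjusted p 0.0449 and 0.045). LDHA, which encodes lactate dehydrogenase A, had 58, 47 and 30 counts in KO and 10, 222 and 96 in WT (adjusted p 0.102), and SMAD3 had an adjusted p of 0.090. The 3 falls were lost without any 1 KO library, and without a low-count filter or at a mean of 5 CPM. LMO4 and MAF were also lost without WT replicate 2 or WT replicate 3, with library totals and with DESeq2, and passed in 4 of 16 alternatives each. These genes are expressed in many other tissues, and the list took 0.198%, 0.198% and 0.452% of counts in WT replicates 1 to 3 against 0.0760% to 0.0891% in KO.

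Targets of p53 and senescence genes showed no gene past the threshold in edgeR. Of 40 p53 targets, 33 were listed and 6 tested, and none (0) changed, over all genes or adjusted over the list alone. MDM2, which encodes the ubiquitin ligase of p53, had 35, 49 and 56 counts in KO and 1, 44 and 82 in WT (log2 fold change −0.36 ± 0.79 SE; adjusted p 0.772). CCNG1 had a log2 fold change of −0.06 ± 0.76 (SE), and the adjusted p of PERP, POLK and ZMAT3 was 0.184, 0.255 and 0.607. CDKN1A, which encodes the cell cycle inhibitor p21, had 10, 9 and 8 counts in KO and 1, 10 and 5 in WT, too few to be tested. CDKN2A had 1 count in each of WT replicates 2 and 3 and 0 in the other libraries. CDKN2B had 52 of its 55 WT counts in WT replicate 2 and 3 counts over the KO libraries. GLB1, the lysosomal β-galactosidase gene, had 7 WT and 9 KO counts. For p53 targets camera gave an adjusted p of 0.626 and for the 6 tested senescence genes 0.812, where RBL2, DPP4, RB1 and IGF1R had adjusted p of 0.294, 0.680, 0.695 and 0.746. On simulated data, which lack the near-identical KO and unlike WT libraries, 8% of 4-fold changes were recovered. A change of that size may therefore have been missed, and the share missed in these data is not known.

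The secretory phenotype of senescent cells and cell division gave the same count of 0 in edgeR, over all genes and adjusted over each list alone. Among 11 tested secretory genes, ANGPT1 had 3 WT and 40 KO counts, a ratio of 8.32 (2.65 to 42.1), with an adjusted p of 0.0551. IGFBP7 had 252 of its 254 WT counts in WT replicate 3 (adjusted p 0.173), and TIMP1 and SPP1 had adjusted p of 0.187 and 0.364. IL6 had 1 WT and 0 KO counts and was not tested. The list's camera adjusted p was 0.626. Of 35 listed cell cycle genes 3 were tested, CCND1, MCM4 and CCND2, with adjusted p of 0.224, 0.550 and 0.868. MKI67, the gene of the proliferation marker Ki-67, had 69 of its 70 WT counts in WT replicate 2 and 4 counts over the KO libraries.

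In central metabolism, 1 gene changed. ENO1, the glycolytic enolase gene, stood at 37.7 ± 10.9 CPM in KO and 413 ± 374 in WT (log2 fold change −3.45 ± 0.83 SE; adjusted p 0.0414), with 12, 207 and 16 counts in the WT libraries, and its call was lost without WT replicate 2 or any 1 KO library, without a low-count filter, at a mean of 5 CPM and with limma-voom, so that it passed in 8 of 16 alternatives. It was 1 of 7 tested glycolysis genes (also adjusted over the list alone), and GAPDH and ALDOA had adjusted p of 0.160 and 0.202. Of 7 tested genes of pyruvate and citrate cycle metabolism none (0) passed, and GLUD1, ACLY, IDH3A and PDP1 had adjusted p of 0.122, 0.262, 0.266 and 0.331. Nuclear genes of oxidative phosphorylation numbered 43 in the table and 5 were tested, none of them (0) past the threshold, with adjusted p of 0.154, 0.287, 0.451 and 0.719 for ATP5B, UQCRC2, UQCRB and NDUFS1. The mitochondrial genes MT-ND2, MT-CO3 and MT-ND5 had adjusted p of 0.192, 0.212 and 0.691. Camera adjusted p was 0.213 for glycolysis, 0.579 for pyruvate and citrate cycle genes and 0.524 for oxidative phosphorylation.

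Stress and inflammation lists gave no call over all genes except among immediate early genes. Of 7 tested redox genes none (0) passed over all genes and 2 were lower adjusted over the list alone, with adjusted p over all genes of 0.071, 0.0846, 0.182 and 0.359 for SOD2, NFE2L2, PRDX1 and PRDX6. None (0) of 13 tested endoplasmic reticulum stress genes passed, with PDIA6, CALR, CANX and SEL1L at 0.0818, 0.177, 0.186 and 0.214. Camera adjusted p was 0.227 and 0.343 for these lists, and the redox list was called lower without WT replicate 3 (0.00806, and adjusted p 0.876 with an estimated correlation). No tested interferon gene (0) passed, and B2M, TAPBP and STAT2 had adjusted p of 0.275, 0.517 and 0.989, and the 2 tested NF-kB genes IL1R1 and NFKBIA 0.296 and 0.368. Of 9 tested immediate early and handling-response genes, JUNB and NR4A1 rose and HSPH1 fell, and adjusted over the list alone 3 were higher and 1 lower. JUNB, which encodes a subunit of the AP-1 transcription factor, stood at 981 ± 30.1 CPM in KO and 136 ± 97.2 in WT (adjusted p 0.0279). NR4A1, a nuclear receptor gene induced by stimulation, had 1 WT and 54 KO counts, a ratio of 33.7 (5.8 to 1360; adjusted p 0.0263), and NR4A2 had an adjusted p of 0.0715. This list had an adjusted p of 0.540 by camera and 0.264 by fry for one direction, and 0.000247 by fry for changes either way. For changes either way, fry also passed the disallowed genes (adjusted p 0.00204) and the exocytosis list (0.0402). The JUNB, NR4A1 and HSPH1 calls were lost without any 1 KO library, and that of NR4A1 also without WT replicate 2. No member (0) of the prolactin response list was tested.

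Among markers of other cell types, S100A8 was the 1 tested myeloid gene, and the myeloid list took 1.72% of counts in WT replicate 2 against 0.0058% to 0.0672% in the other libraries; the fall was lost without WT replicate 2 or any 1 KO library and with limma-voom. GRIA3 of the α-cell list had an adjusted p of 0.464 and LEPR of the δ-cell list 0.430. In the dedifferentiation list HES1, SOX4 and VIM had adjusted p of 0.0736, 0.509 and 0.953. ALDH1A3 of the same list had 26 WT counts, all in WT replicate 2, and 1 KO count. None (0) of 12 tested mesenchymal genes passed (camera adjusted p 0.631), with DCN, COL6A1, MYH11 and LUM at 0.144, 0.282, 0.408 and 0.498. Single tested genes of the endothelial (ENG), Schwann (MBP) and PP and ε-cell (ID4) lists had adjusted p of 0.156, 0.239 and 1.000, and the ductal genes CLU, SPP1 and BICC1 0.0807, 0.364 and 0.348. Adjusted over the list alone, 1 ductal and 1 endothelial gene were higher and 1 myeloid gene was lower, while the α-cell, δ-cell and dedifferentiation lists are given here for single genes only, with no count. With 1 tested gene each, the endothelial and myeloid lists are in effect unadjusted by this step. No acinar, lymphoid, erythroid or adipose gene (0) was deep enough to be tested, and acinar genes took at most 0.0042% of any library's counts.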

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

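The fits with KO columns summed and without WT replicates 2 and 3 were chosen after seeing the data. The 206 changed genes became 205 with DESeq2 size factors, 186 with library totals, 205 with genes over 1% left out of library sizes, and 219 with DESeq2, of which 195, 166, 201 and 145 were shared with the 206. The median log2 fold change of all tested genes was −0.14, against −0.26 with DESeq2 size factors and −0.001 with library totals. The count was 439 without a low-count filter (13702 genes tested), 385 at a mean of 5 CPM, 312 with limma-voom, 766 with WT replicate 1 alone as control, 0 with the KO columns summed, and 0 at an adjusted p of 0.01. Leaving out 1 library gave 3 to 1527 changed genes. The total of 4 PC counts was 0 to 4 without 1 library; the other settings do not act on raw counts.

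The number of gene lists called by camera (1, disallowed genes) was 2 without a filter, 2 at a mean of 5 CPM and 2 with the KO columns summed, where the identity and exocytosis lists were higher and disallowed genes were not called. It was 0 with an estimated correlation in the planned fit and, tried after seeing the data, in every other setting, 0 with WT replicate 1 alone, and 0 to 3 without 1 library. With the replicate number as a block, 137 genes and 3 lists were called. Same-numbered WT and KO libraries had deviations correlated at 0.000, −0.017 and 0.019 across genes, and not every library correlated best with its own number. The KO columns differed by little beyond sampling noise, so this check could hardly have shown pairing and leaves it open.

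Of 512 values of the 33 called named genes under these settings, 326 stayed past the threshold in the same direction, 186 kept the direction without passing and 0 reversed. Most of these genes were chosen because their groups did not overlap, so reversals were unlikely from the start and their absence is no support. Several falls, among them SPINK5, S100A8, HSPA2 and RPL23A, gave no value against WT replicate 1 alone and are not counted there. The block ended the calls of SCN9A, LMO4 and MAF, while MAFA and NR4A2, not called in the planned fit, passed (adjusted p 0.00974 and 0.0275), as they did in 6 and 7 of 16 alternatives in all. LDHA passed without WT replicate 1 only (0.0182). With WT replicate 1 alone as control, the log2 fold change was 2.97 for MDM2 (adjusted p 0.0304; 0.0304 to 1.000 over alternatives) and −0.44 for PAX6 (0.0317; 0.00298 to 1.000), against 0.87 in the planned fit and 3.42 without WT replicate 1 (adjusted p 0.00298) for PAX6. That control is 1 library, with 1 MDM2 count, and the spread is that between the near-identical KO columns, so these values support no call. The cause of the other shifts was not tested. Depth limits the low genes most, with 1 count worth 27.9 CPM in WT replicate 1.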

Other observations

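The tests on oxidative phosphorylation genes, on the ribosomal protein share of WT replicate 2, and on the KO variance were chosen after the results were seen, as were the genes named next and their annotation terms. Further genes that rose in KO libraries included DKK2, a secreted Wnt antagonist gene, from 35.0 ± 24.9 to 1546 ± 114 CPM (SD, n = 3; edgeR adjusted p 0.012), and SLC26A2, a sulfate transporter gene, from 99.6 ± 64.6 to 3245 ± 255 CPM (adjusted p 0.0237). GJD2, the connexin 36 gene that couples β-cells electrically, rose from 64.0 ± 40.2 to 924 ± 78.2 CPM (adjusted p 0.0237). NPAS4, an activity-induced transcription factor gene, rose from 217 ± 146 to 950 ± 18.5 CPM (adjusted p 0.0451). It had 15, 35 and 20 counts in WT replicates 1 to 3, and its WT CPM was highest in WT replicate 1, the shallowest library. CREM had 0, 0 and 2 counts in WT and 30, 27 and 32 in KO (adjusted p 0.0326). UCP2, which encodes a mitochondrial uncoupling protein, had 0, 1 and 0 counts in WT and 61, 69 and 52 in KO (adjusted p 0.0237). Without KO replicate 1 and KO replicate 2, only 3 and 4 genes were called in all, MYH4 and GUCY1A3 among them. Most of the rises in this paragraph were therefore not called in those fits. Of 762 annotation terms tested per direction by a one-sided hypergeometric test on 2499 annotated genes, 0 passed an adjusted p of 0.05.

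The squamous genes of WT replicate 2 and the connective tissue genes of WT replicate 3 stand apart within their genotype, so no biological explanation was tested. RNA of another tissue or of human origin may have entered these libraries. The share of ribosomal protein counts was 0.89 times the mean KO share in WT replicate 3 and 3.29 times it in WT replicate 2, where 86.2% of the ribosomal protein genes exceeded 3 times their KO level. But 65 of the 66 such genes with at least 20 counts there also drew counts from KO libraries, and a small human share would not triple the ribosomal share of WT replicate 3, so the test separates human from mouse RNA in neither library. This test was set aside after its values were seen: by the bounds written before, 0.89 speaks against human RNA in WT replicate 3 and 86.2% against mouse squamous tissue in WT replicate 2. Nuclear oxidative phosphorylation genes left this open too: 2 of the 8 with 0 counts in KO reached 10 counts in WT replicate 2, too few genes for a decision. The bound set for mouse RNA, at most 2 genes, was met. The bound against it, at least 10 genes, could not be met with 8, so this test could not decide. Of the 20 squamous markers 9 exceeded 10 CPM in KO and 2 are in another list, and of the 15 listed connective tissue markers 10 exceeded 10 CPM and 3 are in another list.

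A candidate explanation for GH1 in the KO libraries is a human growth hormone sequence carried by a transgene, since several Cre transgenes used for β-cells contain one; the labels do not name the Cre line. GH1 took at least 99.76% of growth hormone family counts in each KO library. Pituitary RNA would bring other hormone transcripts, but 0 of the 6 pituitary hormone genes set for the test are listed in the table. By the bound written before, under 1% of GH1, that speaks against pituitary RNA. The bound was wrong, since INS, GCG and SST, the hormone genes of islets themselves, are not listed either, so a gene that is not listed may still have been transcribed. Among further pituitary genes, chosen after the results were seen and not all given here, GHRHR, DLK1, PITX1 and CHGB had 0 counts in the KO libraries. GNAS, which islets also express, had 1464, against 21540 for GH1. CHGB is also a member of the β-cell identity list, so its 0 in islet libraries does not speak against pituitary RNA. No pituitary profile was used here to set the counts expected of them, so a transgene and pituitary RNA are not told apart. A response of the islets' own growth hormone gene to the knockout was not tested.

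The 3 KO columns may come from 1 RNA sample. Their variance relative to Poisson noise was nearly flat over abundance, 1.89 for genes with 20 to 50 counts in a pair and 2.14 for genes with at least 300, a quotient of 1.13. Separate animals with a biological coefficient of variation of at least 10% would give about 6.3 at 300 or more counts, above the measured 2.14. Animals that varied by less stay open. If the columns share a sample, the edgeR p-values are too small.

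The 206 genes changed between genotypes compare with 0 as the highest count among the other splits of the 6 libraries into 3 and 3. Only the real split (1 of 10) gave as many, and 10 splits are too few for a share under 0.05. Every other split also puts near-identical KO columns on both sides. Low counts there were to be foreseen, so these splits give no measure of chance. At an unadjusted p under 0.05 in edgeR, the real split gave 729 genes and the other splits 24 to 210.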
